A study of Mus musculus with 12 samples.

How the data were processed

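Total RNA was extracted from mouse skin with TRIzol and made into libraries with a messenger RNA library kit, per the labels' protocols. The 12 libraries were grouped by the sample titles into Ctrl, Model and M+NSPCC1 with 4 each, numbered 01 to 04. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples, which may be in part technical. Doses, treatment times, the age and sex of the mice and the body site are not given in the sources used here.

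The authors deposited, for each library, estimated counts and FPKM values (fragments scaled by transcript length and library depth). The submitters' processing notes name HISAT2 2.2.1, RSEM 1.3.1 and DESeq2 1.34.0 and the genome build mm10, without giving their roles. The deposited count values were not whole numbers in 69.5% of genes (with a tolerance of 0.011 per transcript summed), as estimates that divide reads among transcripts give. The tables held 10720 transcripts of 7902 genes, and 7881 gene IDs matched the reference annotation of the same assembly, which gave the coordinates. Protein-coding genes numbered 7869 of 21900 in that annotation, so the tables cover part of the transcriptome. Of the transcripts tested, 98.3% differed from Ctrl in at least 1 of the comparisons with it, and in M+NSPCC1 against Ctrl 0.511% had an absolute log2 fold change under 0.2. The rule by which transcripts were chosen is not given in the sources used here. A spreadsheet had turned 14 symbols into dates, which were restored from the gene IDs.

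Estimated counts were summed over the transcripts of a gene. Where transcripts of a gene held identical values (402 transcripts of 171 genes), all were kept, since the sums were then whole in 31.6% of those genes and in 0% with the copies dropped. Sums were rounded to whole numbers, which the design fixed before the data were examined allowed for. Totals ran from 9717338 to 10952623. The relative depth of the whole libraries, from the ratio of count to FPKM of the same transcript, ran from 0.9672 to 1.031. Intervals and bounds for counts of 0 (3 counts over the 4 libraries of a group) cover counting error only.

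Tests used R 4.3.3. The main test was edgeR 4.0.16 (quasi-likelihood fit, TMM factors, its default filter by expression), with all 12 libraries in one fit, a coefficient per group and no covariate. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. A positive log2 fold change means higher in the group named first. Model was compared with Ctrl, M+NSPCC1 with Model and M+NSPCC1 with Ctrl. Gene lists (44, of which 37 had the minimum of 4 tested members) were tested with limma 3.58.1 by camera, against the other tested genes with a preset correlation of 0.01, and by fry. A list score was the mean log2 CPM of its members (prior count 2), compared by exact two-sided permutation of 4 against 4 libraries, whose smallest p is 0.0286. None of the tested genes belonged to the lists of mitochondrially encoded and sex-linked genes, which were not analysed here.

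The test, the samples, the gene lists, the alternatives and the genes to be named were chosen before the data were examined, except where stated. Named genes were the 10 largest rises and falls among genes that passed, with a mean of at least 1 CPM and no overlap between the groups, or the 3 with the smallest p per direction where fewer passed. They also included the 4 members with the smallest p of each list that passed, and a fixed set of skin ageing genes, of which Col3a1, Eln, Mmp9, Cdkn1a, Sod2, Krt10 and Flg were tested. Other set members were not analysed here, and some genes that the rule names are not reported here.

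Alternatives were DESeq2's size factors, DESeq2 1.42.0, other filters on low counts (none, or at least 1 CPM in 4 libraries), only the 8 libraries compared, the replicate number as a block, a 2-fold threshold, each library left out in turn, and limma on log2(FPKM + 1) or log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5. On that scale the changes of low genes are understated. Whole-library depth as scaling, transcripts in place of genes, genes with whole sums only, a skeletal muscle covariate and splits of the Model libraries for the count of opposite calls were added after the data had been seen. Comparisons that share libraries were set beside 20 simulated data sets with no effect, and beside simulated data with M+NSPCC1 equal to Model.

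The steps were tested on simulated data with the real means and depths and 200 changed genes per comparison. Genes were drawn independently, with 1 spread per gene shared by all groups, as in the main fit. In the real data the median SD of log2 CPM was 0.242 in Model, 0.147 in Ctrl and 0.145 in M+NSPCC1 libraries (genes with a mean of at least 10 CPM). The rates below may therefore differ from those in the real data. For M+NSPCC1 against Model edgeR recovered 60 of 100 changes of 2-fold and 32 of 100 of 1.5-fold, with 6 false calls among 7638 genes. DESeq2 recovered 74 and 49, with 37 false calls among 7636 genes. Pairs of libraries of a group differed by more than counting noise, with a chi-square per degree of freedom from 12 to 148, so no library was counted as a copy of another.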

Results

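Gene expression was measured by bulk RNA sequencing in 12 mouse skin samples that fell into 3 groups of 4. The Ctrl group was control skin, the Model group came from skin ageing induced by D-galactose together with ultraviolet A and B light, and the M+NSPCC1 group had the same ageing model and the grape seed extract NSPCC1. D-galactose is a sugar given in excess to provoke oxidative and glycation damage. The estimated counts summed to between 9717338 and 10952623 per library over 7902 genes, of which 7638 were tested. These genes were only part of each library, and the sums are not its sequencing depth. The first principal component held 82.8% of the variance and placed the 4 Ctrl libraries between -129 and -114.1 and the other 8 libraries between 35.77 and 89.6. The tables hold mostly transcripts that differ from Ctrl, which favours such a component. Its share therefore holds only within this selection and not for the whole skin transcriptome.

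The comparison of Model with Ctrl asked what the ageing model did to the skin transcriptome. Hair follicle, pigment cell and cell division genes rose in Model skin, and genes of skeletal muscle, vessels, nerve, fat and fibroblasts fell. All 28 tested genes of the hair shaft and inner root sheath rose, with a median log2 fold change of 9.23 (also 9.23 with genes at 0 in Ctrl set at their lower bound), and all 22 skeletal muscle genes fell, with a median of -3.19. Hair shaft genes made up 0.0137% ± 0.0161 of the summed count in Ctrl libraries and 7.47% ± 1.36 in Model libraries (SD, n = 4 each). The Ctrl values rest on Ctrl 02, with 0.0378% against 0.00493% to 0.00694% in the other 3, and without it the median log2 fold change was 12.08 (4 members then had no count in Ctrl). Skeletal muscle genes made up 9.60% ± 0.263 in Ctrl and 1.19% ± 0.699 in Model libraries (SD, n = 4 each). In all, 3753 genes rose and 3160 fell by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05; with DESeq2's size factors 3132 rose and 3238 fell.

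**Figure D1:**
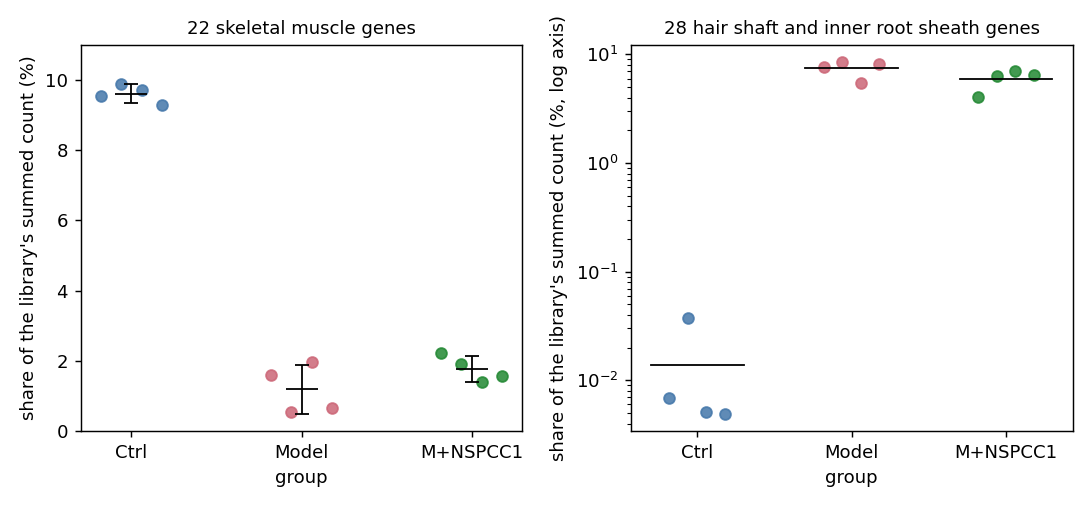
Share of each library's summed count, in percent, held by 22 skeletal muscle genes (left, linear axis) and 28 hair shaft and inner root sheath genes (right, log axis), one point per library in the 3 groups. Bars show the mean, with the SD in the left panel; skeletal muscle genes held 9.28% to 9.89% in the Ctrl libraries and 0.545% to 2.23% in the other 8.

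Among the hair genes, Shh, the signalling protein of the growing follicle (chromosome 5, 28456840 to 28467101), had a scaled count (CPM) of 41.1 ± 6.41 in Model and 0.683 ± 0.368 in Ctrl skin (SD, n = 4 each). Its log2 fold change was 5.89 (SE 0.26; adjusted p = 1.93e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Crym, a hair follicle gene that encodes mu-crystallin, rose by 7.02 and Gprc5d by 10.69 on the log2 scale. In Ctrl 02 Gprc5d had 1.325 CPM, against at most 0.3238 in the other Ctrl libraries. Keratin-associated proteins, which embed the keratin filaments of the hair shaft, gave most of the largest rises. Krtap14, Krtap16-3 and Krtap22-2 lie in a gene cluster on chromosome 16 between 88825291 and 89010759 and reached 1130 ± 447, 1081 ± 517 and 975 ± 233 CPM in Model skin, against at most 0.221 CPM on average in Ctrl (SD, n = 4 each). Krtap19-2, with no count in any Ctrl library, was at least 3670-fold higher, and Tgm6, a transglutaminase, at least 2170-fold higher (bounds from 3 counts over the Ctrl group). Keratins and keratin-associated proteins belong to families of similar sequence, so the split of reads among single members is uncertain. The list as a whole stood above the other genes by camera (Benjamini-Hochberg adjusted p = 1.25e-11), with adjusted p = 0.639 with an estimated correlation.

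Of 13 tested genes of follicle stem cells and the dermal papilla, 9 rose and 4 fell (median log2 fold change 2.42; camera adjusted p = 0.00256, Benjamini-Hochberg). For this list, adjusted p = 0.245 with an estimated correlation. Krt75, a keratin of the follicle's companion layer, rose by 5.43, Corin, a dermal papilla protease, by 5.02, Wif1 by 3.38 and Lhx2 by 3.06 on the log2 scale, while Cd34, Nfatc1, Fgf18 and Crabp1 fell. All 14 tested pigment genes of melanocytes rose (median 6.48; camera adjusted p = 3.02e-06, Benjamini-Hochberg; adjusted p = 0.639 with an estimated correlation). Tyr, the enzyme that begins melanin synthesis, had 179 ± 67.6 CPM in Model and 0.935 ± 0.717 in Ctrl skin (SD, n = 4 each), and Tyrp1 rose by 5.98 and Trpm1 by 8.80 on the log2 scale. In Ctrl 01 Trpm1 had 1.217 CPM, against at most 0.4317 in the other Ctrl libraries. All 28 cell cycle genes rose (median 2.53; camera adjusted p = 8.68e-10, Benjamini-Hochberg; adjusted p = 0.639 with an estimated correlation). Mki67, a marker of dividing cells, had 551 ± 184 CPM in Model and 67.1 ± 7.72 in Ctrl skin (SD, n = 4 each), and Rrm2 rose by 2.07, Mcm5 by 1.86 and Hmmr by 2.53 on the log2 scale.

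The 22 skeletal muscle genes fell nearly alike, with an interquartile range of 0.224 on the log2 scale (camera adjusted p = 4.19e-07, Benjamini-Hochberg; adjusted p = 0.639 with an estimated correlation). Ttn, the giant sarcomere protein (chromosome 2, 76703980 to 76982557), had 211 ± 105 CPM in Model and 2342 ± 223 in Ctrl skin (SD, n = 4 each), and the log2 fold changes of Neb, Tnni2 and Cacna1s were -3.32, -3.31 and -3.15. Of the Schwann cell and nerve genes 11 of 12 fell, 1 rose (Fabp7), and the median was -2.22 (camera adjusted p = 0.000706, Benjamini-Hochberg; adjusted p = 0.639 with an estimated correlation). Mbp, which encodes myelin basic protein, fell by 2.40 on the log2 scale. All 9 smooth muscle and pericyte genes fell (median -2.07, camera adjusted p = 0.00296), as did all 11 endothelial genes (-1.79, 0.00522), all 10 adipocyte genes (-1.78, 0.0032) and all 13 fibroblast genes (-1.60, 0.00256), with Benjamini-Hochberg adjustment. For each of these 4 lists, adjusted p = 0.639 with an estimated correlation. The 4 lists held 13, 15, 19 and 18 genes, and members that were not tested may include some that did not change. Among all tested genes 90.5% passed in this comparison, in either direction. Log2 fold changes were -3.09 for Des, an intermediate filament protein of smooth and skeletal muscle, -1.59 for the vascular receptor Kdr, -1.98 for the glycerol phosphate dehydrogenase Gpd1, and -2.12 and -1.37 for the fibroblast genes Pi16 and Dpp4. Slc2a4, the insulin-regulated glucose transporter of fat and muscle, fell by 2.81 on the log2 scale.

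All 28 tested nuclear genes of oxidative phosphorylation fell (median -0.86; camera adjusted p = 8.68e-10, Benjamini-Hochberg; adjusted p = 0.639 with an estimated correlation). Log2 fold changes were -1.01 for Ndufs1 of complex I, -0.98 for Sdhb of complex II and -0.99 for Cox5a of complex IV. These genes are abundant in muscle, whose share of the counts fell in the same libraries. Of 19 antioxidant genes 14 fell and 4 rose (median -0.92; camera adjusted p = 0.025, Benjamini-Hochberg; adjusted p = 0.639 with an estimated correlation). Adjusted over the list alone, 5 rose and 14 fell. Sod1, Prdx3 and Gpx4, which detoxify superoxide, hydrogen peroxide and lipid peroxides, had log2 fold changes of -1.21, -1.12 and -1.24, and Gpx2, Prdx2 and the metallothioneins Mt1 and Mt2 rose. Of 19 interferon-stimulated genes 16 fell and 3 did not pass (median -1.55; camera adjusted p = 0.0374, Benjamini-Hochberg; adjusted p = 0.705 with an estimated correlation). Log2 fold changes were -1.07 for Stat2, -1.99 for Bst2 and -1.34 for Ifih1. Bst2 had 213.1 CPM in Ctrl 01 and 73.83 to 99.83 in the other Ctrl libraries, and without Ctrl 01 the list median was -1.21. The call on the interferon list was lost with DESeq2's size factors (adjusted p = 0.0776) and without the library Model 02 (adjusted p = 0.0669, camera with Benjamini-Hochberg). For the other 12 lists that passed, the counts adjusted over the list alone equalled those over all genes tested.

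Genes often measured in aged skin went in different directions. Eln, which encodes elastin, had 143 ± 65.4 CPM in Model and 653 ± 113 in Ctrl skin, and Col3a1, a fibrillar collagen chain, 4215 ± 1667 against 7655 ± 846 (SD, n = 4 each). Their log2 fold changes were -2.19 (SE 0.28; adjusted p = 2.1e-05) and -0.86 (SE 0.24; adjusted p = 0.00471) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Log2 fold changes were -1.82 for Krt10, a keratin of the suprabasal epidermis, -1.74 for the gelatinase Mmp9, -0.54 for the mitochondrial superoxide dismutase Sod2 and 0.66 for Cdkn1a, which encodes an inhibitor of the cell cycle. Mmp9 had 31.65 CPM in Model 03 and 5.653 to 10.32 in the other Model libraries. Flg, which encodes filaggrin, had a log2 fold change of 0.48 (SE 0.21; adjusted p = 0.046 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). That call did not hold with DESeq2's size factors or without any one of 6 libraries. Of the largest falls, Serpina3j and Samd12 had no count in any Model library and were at least 137-fold and 86.3-fold lower than in Ctrl (bounds from 3 counts over the Model group). Each was measured through 1 transcript whose estimated counts were not whole numbers, so the values describe that transcript.

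**Figure D2:**
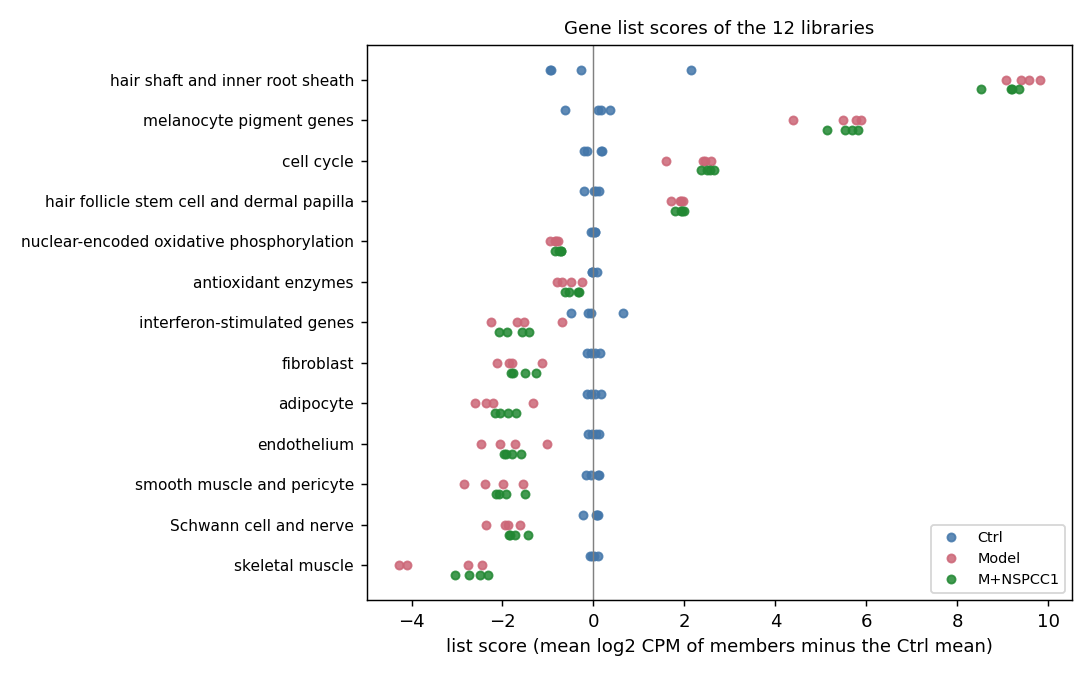
Score of each gene list that passed in Model against Ctrl, as the mean log2 CPM of its tested genes minus the mean over the Ctrl libraries, one point per library coloured by group. In each list the Model and M+NSPCC1 libraries lie on one side of the Ctrl libraries. They are furthest for the hair shaft list, whose score was 9.47 higher in Model than in Ctrl on average (10.19 without Ctrl 02), while for interferon-stimulated genes Model 03 at -0.70 is nearer to Ctrl 04 at -0.49 than to the other Model libraries.

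The median log2 fold change of all tested genes was 0.255 with TMM scaling, 0.083 with DESeq2's size factors and 0.432 with the relative depth of the whole libraries. Relative to it, the medians were 8.97 for hair shaft, 2.28 for cell cycle, -1.11 for oxidative phosphorylation and -3.44 for skeletal muscle genes, and no list that passed changed direction under the 3 scalings. Of the transcripts tested, 98.3% differed from Ctrl in at least 1 of the comparisons with it, so counts of changed genes and tests of a list against other genes hold only within this selection.

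The comparison of M+NSPCC1 with Model asked what the grape seed extract changed in the ageing model. No gene passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where 502 genes had an unadjusted p under 0.05 against 382 expected by chance and the smallest adjusted p was 0.0806. DESeq2 called 74 genes, 16 higher and 58 lower in M+NSPCC1, and limma on log2 FPKM called 0. Skeletal muscle genes lay higher in M+NSPCC1 (median log2 fold change 0.56; 0.33 without Model 02 and 0.90 without Model 03) and hair shaft genes lower (median -0.36; -0.22 without M+NSPCC1 01), but none of the 22 and 28 members passed. Their shares of the summed count were 1.78% ± 0.367 and 5.97% ± 1.31 in M+NSPCC1, where single Model libraries ranged from 0.545% to 1.97% and from 5.50% to 8.48% (SD, n = 4). M+NSPCC1 01 lay outside both ranges, with 2.23% and 4.05%.

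Of 37 lists tested, 6 passed camera in this comparison with Benjamini-Hochberg adjustment, 3 of them above and 3 below the other genes. The adjusted p was 1.1e-09 for skeletal muscle, 0.000354 for cell cycle (median 0.18), 0.000682 for oxidative phosphorylation (0.11), 0.0112 for hair shaft, 0.0207 for immediate early genes (-0.12) and 0.0495 for heat shock and unfolded protein response genes (-0.11). For each of the 6, adjusted p = 0.871 with an estimated correlation. Of the 6, skeletal muscle alone also passed with each library left out in turn. The call was lost for cell cycle without Model 03 (adjusted p = 0.813), for hair shaft without Model 02 (0.223) or M+NSPCC1 01 (0.178) and for oxidative phosphorylation without Model 04 (0.0672), by camera with Benjamini-Hochberg adjustment. It was lost for immediate early genes without Model 01, Model 02, M+NSPCC1 02, M+NSPCC1 03 or M+NSPCC1 04 (0.0633 to 0.167). For heat shock and unfolded protein response genes it was lost with DESeq2's size factors (0.0567) and without any library but Ctrl 03, Model 02 and Model 04 (0.0514 to 0.298). None of their members passed over all genes tested; adjusted over the list alone, 1 hair shaft gene and 1 heat shock and unfolded protein response gene fell, and no member of the other 4 lists passed. Exact two-sided permutation tests of the list scores of 4 against 4 libraries gave p = 0.257 for skeletal muscle and p = 0.171 for hair shaft. The lowest exact permutation p was 0.0286 for the heat shock and unfolded protein response list, the smallest such a test can give, with a score difference of -0.18 and an adjusted p of 0.868 over 37 lists.

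The genes nearest to passing gave values that did not pass. Ntn4, a secreted laminin-related protein, had 37.5 ± 2.2 CPM in M+NSPCC1 and 59.4 ± 7.59 in Model skin, Tent5b 160 ± 22.3 against 248 ± 16.5 and Ppfibp2 50.9 ± 4 against 71.8 ± 4.26 (SD, n = 4 each). The adjusted p of each was 0.0887 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and DESeq2 called all 3. Kcnab1, Ppp1r26 and Xiap had no count in any Model library and 1.05 ± 0.431, 7.63 ± 2.08 and 3.9 ± 2.72 CPM in M+NSPCC1 (SD, n = 4), each through 1 transcript with estimated counts that were not whole numbers; DESeq2 called all 3. Within the hair list, Shh had 62.4 ± 8.29 CPM against 41.1 ± 6.41 in Model, and Krt84 22.3 ± 5.87 against 67.2 ± 37.6 (SD, n = 4 each; adjusted p = 0.548 and 0.36 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). DESeq2 called both (adjusted p = 0.0272 and 0.0346, Benjamini-Hochberg). Chac1, a glutathione-degrading enzyme of the stress response, had 92.0 ± 14.1 against 160 ± 62.1 CPM and Egr1, an immediate early transcription factor, 226 ± 17.0 against 308 ± 6.42 (SD, n = 4 each).

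Matrix and ageing genes did not pass either. Log2 fold changes of M+NSPCC1 over Model were 0.05 (SE 0.23) for Col3a1, -0.10 (SE 0.27) for Eln, -0.57 (SE 0.50) for Mmp9, 0.01 (SE 0.09) for Sod2 and 0.23 (SE 0.27) for Krt10. Single libraries moved these values, for some across 0: without Model 03 they were 0.25 for Eln, 0.21 for Mmp9, -0.05 for Sod2, 0.33 for Col3a1 and 0.59 for Krt10, and without Model 02 that of Col3a1 was -0.12 and that of Krt10 0.09. Cdkn1a had 479 ± 24.7 CPM against 557 ± 28.1 and Flg 547 ± 141 against 350 ± 69.98 (SD, n = 4 each), with adjusted p = 0.674 and 0.605 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The 95% interval of the log2 fold change excluded a 2-fold change in either direction for 77.1% of the tested genes and a 1.5-fold change for 54.7%. Without the library Model 03, 5 genes passed and 10 lists did; without M+NSPCC1 01, 4 genes passed.

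Whether the extract moved expression back towards Ctrl was examined through genes that changed in the model and changed the other way with the extract. No gene passed both comparisons by edgeR's quasi-likelihood test, with either opposite or equal signs, while DESeq2 gave 40 with opposite signs and edgeR 4 without Model 03. DESeq2's count with equal signs was not taken, so 40 alone does not show a move back towards Ctrl. Of genes that passed Model against Ctrl by edgeR, 57.2% had opposite signs without having to pass the other comparison. Simulated groups in which M+NSPCC1 equalled Model gave 52.1%. Across genes, which are not independent replicates, the covariance of the log2 fold changes of Model over Ctrl and M+NSPCC1 over Model was -0.167 (Pearson r = -0.0929); it was -0.597 without Model 03 and -0.041 without Model 02. Both comparisons use the same Model libraries, and simulated groups with no effect gave -0.0969. Simulated groups in which Model differed from Ctrl and M+NSPCC1 equalled Model gave -0.102 (Pearson r = -0.0918). The jackknife SE of the observed covariance, from leaving out libraries, was 0.377. With the Model libraries split so that each comparison had its own pair, the mean covariance over 6 splits was -0.00484, from -0.428 to 0.448, and the splits gave 0 to 225 genes with opposite signs.

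The comparison of M+NSPCC1 with Ctrl asked what still differed from control skin in animals given the extract. Gene groups that changed in Model skin also changed here. All 28 hair shaft genes (median log2 fold change 8.96, and 11.68 without Ctrl 02), all 14 pigment genes (6.65) and all 28 cell cycle genes (2.74) rose, and all 22 skeletal muscle genes fell (-2.66). In all, 3826 genes rose and 3291 fell by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05; with DESeq2's size factors 3234 rose and 3326 fell. Of the follicle stem cell and dermal papilla genes 9 rose and 4 fell (2.51). Schwann cell and nerve genes (11 of 12 fell, median -2.05), smooth muscle and pericyte genes (9 of 9, -1.88), endothelial genes (11 of 11, -1.82), adipocyte genes (10 of 10, -1.75), interferon-stimulated genes (19 of 19, -1.72), fibroblast genes (12 of 13, -1.63), antioxidant genes (14 of 19, with 4 that rose, -0.83) and oxidative phosphorylation genes (28 of 28, -0.75) fell. For these 13 lists the counts adjusted over the list alone equalled those over all genes tested. Among all tested genes 93.2% passed in this comparison, in either direction. All 13 passed camera with Benjamini-Hochberg adjusted p values from 6.94e-12 for cell cycle to 0.0326 for antioxidant genes, whose call was lost without Model 02 (0.0508). For 11 of them adjusted p = 0.63 with an estimated correlation, and it was 0.268 for the follicle list and 0.646 for the interferon list.

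Shh had 62.4 ± 8.29 CPM in M+NSPCC1 and 0.683 ± 0.368 in Ctrl skin, Msx2, a homeobox gene of the hair matrix, 301 ± 55.0 against 3.12 ± 1.37, and Mki67 634 ± 44.3 against 67.1 ± 7.72 (SD, n = 4 each). Acta1, the actin of skeletal muscle, had 3750 ± 672 CPM against 25450 ± 1031, and Sdha of complex II 426 ± 4.96 against 862 ± 58.1 (SD, n = 4 each). Log2 fold changes were -2.68 for Oas2, an antiviral enzyme induced by interferon, -2.01 for Bst2 and -3.22 for Thrsp, a regulator of fat synthesis. In Ctrl 01 Oas2 and Bst2 had 93.12 and 213.1 CPM, against at most 53.79 and 99.83 in the other Ctrl libraries. Log2 fold changes of Eln, Col3a1, Krt10, Mmp9 and Sod2 were -2.29, -0.81, -1.59, -2.31 and -0.54, while Cdkn1a rose by 0.44 and Flg by 1.12. Ncapg2, a condensin subunit that compacts chromosomes, had no count in Ctrl and was at least 475-fold higher, and Il1rl1, the receptor of interleukin 33, had none in M+NSPCC1 and was at least 169-fold lower (bounds from 3 counts over the group). Both belong to 235 genes with no count in 1 group and at least 100 in another, of which 213 were measured through 1 transcript. Their values may thus describe a transcript and not the whole gene.

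Of the genes changed in either comparison with Ctrl, 3606 were higher in both and 3136 lower in both, where independent lists would share 1880 and 1362, and 0 had opposite signs. The lists are not independent, since both comparisons use the same Ctrl libraries and the tables hold mostly transcripts that differ from Ctrl. The numbers 1880 and 1362 are therefore no measure of chance. A further 171 passed only for Model and 375 only for M+NSPCC1, and the direct comparison above found none of these to differ by edgeR's quasi-likelihood test. The covariance of both sets of log2 fold changes was 5.83 (Pearson r = 0.956 across genes), against 0.0936 in simulated groups with no effect that shared the Ctrl libraries. That simulated value is no baseline for tables that hold mostly transcripts that differ from Ctrl. Simulated groups in which M+NSPCC1 equalled Model gave 6.12 (Pearson r = 0.984). With separate pairs of Ctrl libraries for each comparison, the observed covariance averaged 6.18 over 6 splits.

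**Figure D3:**
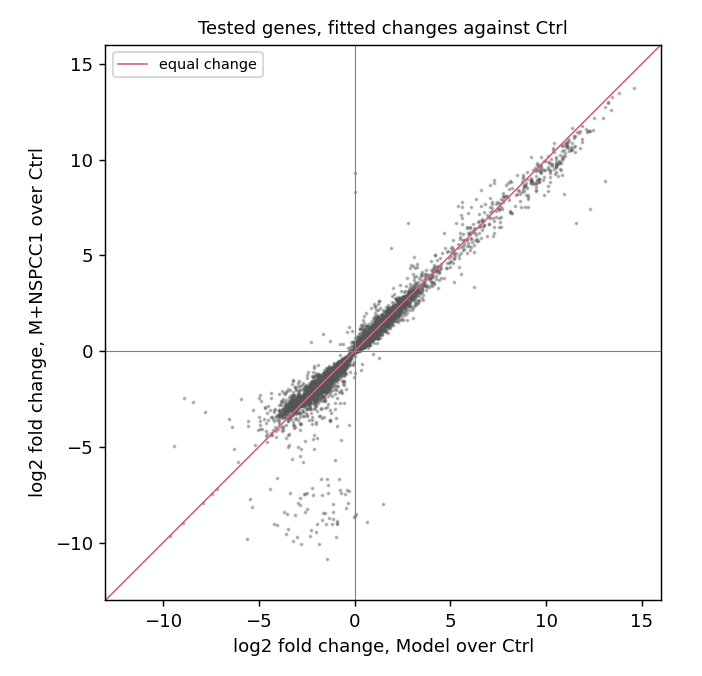
Fitted log2 fold changes of 7638 tested genes for Model over Ctrl (horizontal) and M+NSPCC1 over Ctrl (vertical), one point per gene, with the line of equal change. Points lie along the line, with a covariance of 5.83. Simulated groups with M+NSPCC1 equal to Model gave 6.12, and simulated groups with no effect gave 0.0936. Points far below the line include genes with no count in M+NSPCC1, such as Il1rl1.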

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

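The comparison of hair shaft with endothelial genes, the interval test of 2-fold changes, the density of small changes, the skeletal muscle covariate, the splits at an unadjusted p and the comparison of their muscle shares were chosen after the data had been seen; the other tests of an explanation were chosen after the first results per gene but before their own values were seen, and the splits into 4 and 4 and Dixon's limit before the data were examined.

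Against Ctrl, hair shaft genes rose and skeletal muscle genes fell in both Model and M+NSPCC1 skin. A lower share of muscle that raises every other transcript alike is argued against in Model against Ctrl, since the hair shaft median lay 11.02 above the endothelium median on the log2 scale, with a larger SD of members of 2.226. A smaller part of skeletal muscle in the Model and M+NSPCC1 samples remains open: all 22 muscle genes fell, with an interquartile range of 0.224, and none belongs to another list. Hair follicles in a growth phase in those samples and not in Ctrl also remain open, since the lower of the cell cycle and pigment medians lay 2.279 above the median of all tested genes (SD of members 0.68). On average over the Ctrl libraries, 21 of 28 hair shaft genes, 6 of 14 pigment genes and 27 of 28 cell cycle genes exceeded 1 CPM. These counts were not taken without Ctrl 02, where hair shaft genes held 0.0378% of the summed count, against 0.00493% to 0.00694% in the other Ctrl libraries. An effect of the ageing model on muscle or on hair growth stays open as untested, because it separates the same groups as the tissue makeup and the phase of the follicles.

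No gene passed between M+NSPCC1 and Model by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, where 502 had an unadjusted p under 0.05, DESeq2 called 74 and limma on log2 FPKM 0. Uneven skeletal muscle content of the Model libraries as what hides differences stays open: with the skeletal muscle score as a covariate 0 genes passed, but the number with an unadjusted p under 0.05 was 1006, against 441 in the fit of the same 8 libraries without it. At the power found on simulated data, a count of 0 does not argue against it, although fewer than 50 genes had been set as the bound after the data had been seen and before this fit was run. Too little power at 4 against 4 libraries stays open, with 60% of simulated 2-fold changes recovered and a 95% interval that excluded a 2-fold change either way for 77.1% of the tested genes. An extract with little effect on these genes stays open as untested.

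Nearly every tested gene differed from Ctrl. Transcripts chosen for a difference from Ctrl before the tables were made may account for this: in M+NSPCC1 against Ctrl the density of absolute log2 fold changes under 0.2 was 0.0468 of the density between 0.4 and 0.8. A broad effect of the ageing model on the skin stays open as untested, and a choice of transcripts does not exclude it.

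The 8 libraries of each comparison can be split into 4 and 4 in 35 ways. For genes changed in Model against Ctrl, 1 of 35 splits, the real one, gave as many as the 6913 genes, and the highest of the others gave 0. For M+NSPCC1 against Ctrl, 1 of 35 splits reached the real 7117 genes and the highest other gave 0. Neither count can exclude chance, because transcripts chosen for a difference from Ctrl would favour the real split whatever its cause. For genes between M+NSPCC1 and Model this count says nothing about chance, because the real number is 0 and any split (35 of 35) gives at least that many; the highest other gave 2. By the number of gene lists that passed camera, chance cannot be excluded. As many lists as the real 13 came in 19 of 35 splits for Model against Ctrl (highest other 17), as many as the real 6 in 26 of 35 for M+NSPCC1 against Model (highest other 17), and as many as the real 13 in 16 of 35 for M+NSPCC1 against Ctrl (highest other 16). Of the other splits that reached these numbers, 15 of 18 for Model against Ctrl and 15 of 15 for M+NSPCC1 against Ctrl kept 3 libraries of a group together. So did 11 of 25 for M+NSPCC1 against Model. Such splits carry part of any difference between the groups, and between M+NSPCC1 and Model no gene passed by edgeR. At an unadjusted p under 0.05, the split of M+NSPCC1 01, M+NSPCC1 02, Model 01 and Model 03 from the other 4 libraries gave 1523 genes against 502 in the real split, and 13 of 35 splits gave at least 502. The split with 1523 genes points to a structure of the samples within these groups. Its 4 libraries held the 4 highest shares of skeletal muscle genes, 1.59% to 2.23% of the summed count, against 0.545% to 1.57% in the others. By the skeletal muscle list score M+NSPCC1 04 (-2.739) lay above Model 01 (-2.765), so muscle content moved with this split only in part. The labels give no batch for it.

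Single libraries stood apart from the other 3 of their group where the gap to the nearest library exceeded Dixon's 95% critical value, as a share of the group's range. Chance puts about 1 in 20 groups beyond this limit. That is about 1 of 15 groups for library measures, 6 of 111 for list scores and 18 of 360 for named genes, where 1, 4 and 31 were found, and members of 1 list or library are not independent. For named genes 18 is no chance level, because a gene with counts in only 1 library of a group exceeds the limit at any count. Krtap12-1, at 0.11 CPM in Ctrl 02 and 0 in the other Ctrl libraries, is such a gene.

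In Ctrl 02, hair shaft genes made up 0.0378% of the summed count, against 0.00493% to 0.00694% in the other Ctrl libraries. The same library held 1.44 CPM of Krt33b, 0.884 of Krtap16-3, 0.773 of Krtap14, 0.442 of Krtap22-2, 0.221 of Krtap19-5, 0.221 of Oca2 and 0.11 of Krtap12-1, and the other 3 Ctrl libraries held 0 of each. The score of hyaluronan genes in Ctrl 03 was 0.367, against -0.136 to -0.0979 in the others. The score of stress-induced keratinocyte genes and alarmins in Ctrl 03 was 0.826, against -0.348 to -0.167. In Ctrl 04, the Schwann cell and nerve score was -0.236, against 0.0512 to 0.1, Cdkn1a had 410 CPM against 329 to 342, and the stress-induced transcription factor Atf3 had 109 CPM against 46.3 to 53. Ifih1 had 41.5 CPM in Ctrl 01, against 49.0 to 49.7.

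In Model 03, Krtap20-2 had 231 CPM against 2.94 to 6.15 in the other Model libraries, Gpd1 488 against 252 to 268, Mfap5 113 against 53.5 to 62.4, Cmpk2 21.1 against 7.39 to 8.85 and Cidec, a lipid droplet protein, 10.5 against 2.94 to 4.01. Fam118b had 7.44 CPM, Islr2 1.59 and Snap23 0.595 in Model 03, and 0 in the other 3. Hamp2 had 0 CPM in Model 03 and 0.0927 to 0.0947 in the others. Sbk1 had 0.947 CPM in Model 01 and 0 in the others, and Tent5b had 224 CPM in Model 01 against 254 to 259. Mast3 had 6.3 CPM and Osbpl6 0.834 in Model 02, with 0 in the other Model libraries.

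In M+NSPCC1 01, the score of aquaporins, ceramide and lipid barrier enzymes was -0.0352, against -0.439 to -0.398 in the other M+NSPCC1 libraries. Junb had 450 CPM there against 258 to 275, Ndufs1 173 against 157 to 159 and Xiap 7.98 against 2.41 to 2.66. The Krtap19 genes were lower in that library, with 111 CPM of Krtap19-5 against 210 to 225, 111 of Krtap19-2 against 181 to 191 and 44.1 of Krtap19-1 against 83.8 to 85.4. In M+NSPCC1 02, Tbc1d8 had 1.02 CPM and Sun1 0.927, and the other 3 libraries held 0 of both.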

How the results depend on the processing

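Whole-library depth, transcripts in place of genes, genes with whole sums, the skeletal muscle covariate and the split of the Model libraries for opposite calls were chosen after the data had been seen. For genes changed against Ctrl, the counts of 6913 (Model) and 7117 (M+NSPCC1) stayed within 1.5 times under other scalings, filters and tools, except where fewer genes could pass: 4002 and 4097 with a 2-fold threshold, and 2276 and 2295 among genes with whole sums. The balance of directions turned: 3753 genes rose and 3160 fell in Model against Ctrl, against 3132 and 3238 with DESeq2's size factors, 3222 and 3315 with DESeq2 and 1749 and 2253 with a 2-fold threshold. In M+NSPCC1 against Ctrl the numbers were 3826 and 3291, against 3234 and 3326, 3369 and 3422, and 1763 and 2334. Between M+NSPCC1 and Model edgeR called 0 genes (502 at an unadjusted p under 0.05) and limma on log2 FPKM 0; DESeq2 called 74 and edgeR 2 (Atp2c2 and Ppp1r26) with only the 8 libraries compared. Genes passing Model against Ctrl and M+NSPCC1 against Model with opposite signs numbered 0, against 40 with DESeq2, where those with equal signs were not counted. With the Model libraries split the number was 38 on average, where the 6 splits ran from 0 to 225 and 1 split gave nearly all of the average. Lists passing by camera numbered 13, 6 and 13 (Model against Ctrl, M+NSPCC1 against Model, M+NSPCC1 against Ctrl), against 0, 0 and 0 with an estimated correlation and 33, 0 and 32 by fry, which does not compare a list with other genes. The cause of these differences was not tested, apart from the smaller number of genes or samples.

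Leaving out each library in turn gave 6723 to 7018 genes for Model against Ctrl, 0 to 5 for M+NSPCC1 against Model and 6899 to 7268 for M+NSPCC1 against Ctrl. It gave 0 to 4 genes with opposite signs, a covariance from -0.597 to -0.041, and 12 to 16, 4 to 10 and 13 to 17 lists. Without Model 03, 5 genes passed between M+NSPCC1 and Model (Aqp4, Kcnab1 and Ppp1r26 higher, Pthlh and Stbd1 lower), 4 of them opposite to Model against Ctrl, 10 lists passed and the covariance was -0.597; without Model 02 it was -0.041. Without M+NSPCC1 01, 4 genes passed (Kcnab1 higher, Zfp14, Gm39972 and Gm42368 lower). These genes are named after their values were seen. No named gene that passed and no list that passed reversed its direction under the settings that gave it a value; the direction of each of the other called genes was not compared.

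The replicate number as a block gave 6823, 0 and 7027 genes and 13, 6 and 13 lists. The numbers did not pair the samples: of 12 same-numbered pairs 1 had a correlation of deviations over 0.1 (-0.162 to 0.119), and 2 of 12 libraries (Model 01 and M+NSPCC1 01) correlated best with a library of their own number. Deposited totals of 9717338 to 10952623 cover part of each library. Counting depth limits the folds of named genes with no count in a group, and also of those with few, such as Oca2 and Krtap19-5 with 2 counts over the Ctrl group, Krtap22-2 with 4, and Hamp2 and Sun1 with 3 and 4 over the Model group.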

Other observations

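No test here was chosen after the result was seen, except the count of genes at 0 in a group and the scaling by whole-library depth; the gene lists were fixed before the data were examined, and the single genes named were chosen after their values were seen.

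Beyond the groups described above, lists of matrix, immune and lipid genes moved in part against Ctrl in Model skin without passing camera (Benjamini-Hochberg) with all 12 libraries. Without Model 03, elastic fibre and proteoglycan (adjusted p = 0.00687), dendritic and Langerhans cell (0.0048) and sebaceous gland genes (0.0428) did pass camera, as did dendritic and Langerhans cell genes with whole-library depth (0.0411). With all 12 libraries, adjusted p = 0.705, 0.705 and 0.639 for these lists with an estimated correlation. Of 18 elastic fibre and proteoglycan genes 13 fell and 4 rose (median log2 fold change -1.25; camera adjusted p = 0.0793). The log2 fold changes were -1.69 for Fbn1, the fibrillin of adult microfibrils, and -2.10 for Loxl1, a cross-linking enzyme of elastin, while Fbn2, the fibrillin of developing tissue, rose by 1.93. Of 7 collagens 4 fell and 2 rose (camera adjusted p = 0.564), of 5 matrix proteases 3 fell (0.533), and the 3 metalloproteinase inhibitors tested as single genes all fell. Of 5 hyaluronan genes 4 rose and 1 fell (camera adjusted p = 0.276); the synthase Has3 rose by 1.78 and Cemip, which takes part in hyaluronan breakdown, by 3.41. Of 13 macrophage genes 11 fell and 2 rose (median -1.72; camera adjusted p = 0.128), the risers being Gpnmb by 3.09, a gene that pigment cells also express, and Arg1 by 1.84. Of 8 dendritic and Langerhans cell genes 7 fell (median -1.46; 0.0729), of 5 T and NK cell genes 3 fell and 1 rose (0.564), and of 4 mast cell genes 2 fell and 1 rose (0.834). Of 8 sebaceous gland lipid genes 5 fell and 3 rose (median -1.86; 0.174), with -2.93 for the fatty acid synthase Fasn and -2.38 for Acly, and of 7 cholesterol synthesis genes 3 fell and 2 rose (0.572).

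Keratinocyte, stress and clock genes went both ways in Model against Ctrl. Of 9 stress-induced keratinocyte genes and alarmins 5 rose and 1 fell (camera adjusted p = 0.198, Benjamini-Hochberg; adjusted over the list alone, 4 rose), of 13 cornified envelope genes 7 rose and 5 fell (0.564), and of 9 basal keratinocyte genes 5 rose and 2 fell (0.198). Of 11 targets of NRF2, a regulator of antioxidant defence, 5 rose and 6 fell (0.564); the cystine transporter Slc7a11 rose by 6.38 and Gclc, an enzyme of glutathione synthesis, by 1.91, while Me1 fell by 2.77 on the log2 scale. Of 13 p53 and DNA damage genes 8 rose and 4 fell (0.66), of 10 senescence genes 5 rose and 4 fell (0.834), of 7 galactose and glycation genes 4 fell and 2 rose (0.564), and of 7 TGF-beta genes 4 rose and 3 fell (0.66). Of 9 immediate early genes 7 rose and 2 fell (0.377), of 9 heat shock and unfolded protein response genes 4 rose and 5 fell (0.834), of 14 autophagy and lysosome genes 5 rose and 8 fell (0.564; adjusted over the list alone, 9 fell), and of 7 aquaporin and lipid barrier genes 4 rose and 3 fell (0.948). Of 7 circadian clock genes 5 fell and 2 rose (median -1.41; camera adjusted p = 0.388, Benjamini-Hochberg). The clock regulators Nr1d1, Dbp and Tef had log2 fold changes of -2.60, -2.03 and -1.48, and Cry1 and Nfil3 rose by 1.05 and 1.42; times of sampling are not given in the sources used here. Of 26 ribosomal protein genes 21 rose and none fell (median 0.42; camera adjusted p = 0.108, Benjamini-Hochberg), with a median of 0.25 with DESeq2's size factors and 0.60 with whole-library depth, and 0.17 above the median of all tested genes. With whole-library depth the ribosomal list passed camera (adjusted p = 0.0411, Benjamini-Hochberg); with TMM scaling, adjusted p = 0.706 with an estimated correlation. Median and mean differed in sign for TGF-beta (0.26 and -0.06), NRF2 (-1.01 and 0.18), heat shock (-0.71 and 0.02) and aquaporin genes (0.18 and -0.86).

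Of lists with fewer than 4 tested members, inflammatory cytokines, neutrophil genes and B cell genes each had 1 of 2 that rose and 1 that fell in Model against Ctrl, and the 1 erythroid gene rose. Between M+NSPCC1 and Model no member of any list passed over all genes tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone, 1 cholesterol synthesis gene rose and 1 fell, and 1 gene each of the galactose, autophagy and erythroid lists fell. Some lists passed camera (Benjamini-Hochberg) in this comparison only with 1 library left out. Without Model 03 these were elastic fibre and proteoglycan (adjusted p = 1.51e-05), adipocyte and fibroblast (0.00155 each), smooth muscle and pericyte (0.00338), dendritic and Langerhans cell (0.00895, with a direction opposite to that with all libraries) and Schwann cell and nerve genes (0.0391). Without Model 02 they were ribosomal protein (0.000253), interferon-stimulated (0.0074), endothelial (0.0245), TGF-beta and macrophage genes (0.0318 each). Macrophage genes also passed without M+NSPCC1 02 (0.0304), autophagy genes without Model 04 (0.0294) or M+NSPCC1 01 (0.0453), and stress-induced keratinocyte genes without M+NSPCC1 01 (9.05e-05). With all 12 libraries, the adjusted p of these lists was 0.871 to 0.981 with an estimated correlation.

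DESeq2 called 74 genes between M+NSPCC1 and Model at a Benjamini-Hochberg adjusted p under 0.05, where edgeR called 0. Among them, log2 fold changes were -0.56 for the desmosomal cadherin Dsc2, -0.36 for Tjp1, a tight junction protein, -0.91 for Padi1, an enzyme that modifies keratinocyte proteins, -0.85 for Pthlh and -1.53 for Car6, and 1.296 for Hsd11b2 and 0.25 for Park7, a protein of oxidative stress defence. Others of the 74 had extreme values, such as -23.52 for Fnip1, -22.19 for Zkscan8 and 21.85 for Plec. Whether the called genes share a function was not tested. On simulated data for this comparison, with genes drawn independently and the same spread in all groups, DESeq2 gave 37 false calls and edgeR 6.

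A set of 235 genes had no count in 1 group and at least 100 counts in another, 145 of them with none in Ctrl, 57 in Model and 86 in M+NSPCC1. Of these, 213 were measured through 1 transcript, and 92.8% had estimated counts that were not whole numbers, against 69.5% of all genes. They include Kcnab1, Ppp1r26 and Xiap, which had no count in any Model library.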
